A study of Mus musculus with 16 samples.

How the data were processed

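RNA was measured in 16 mouse liver samples that the labels place in 4 groups of 4. AUG livers carried a mouse telomerase RNA gene (Terc) labelled CUG/AUG, and del7 livers carried a Terc lacking 7 nucleotides at positions 29 to 35. Each mutant had a wild-type group of its own, called AUG_WT and del7_WT here. Per the labels' protocols, 10 mg of disrupted frozen tissue and 550 ng of DNase-treated total RNA went into each library, ribosomal RNA was depleted, and a directional kit that keeps the strand was used. The label does not say whether CUG/AUG names a replaced codon or a pair of alleles, so the text keeps the label. The labels give no sequencing batch or date.

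Per the submitters' processing notes, reads were trimmed with cutadapt 2.10 and aligned with STAR 2.7.9a to GRCm39. The annotation release is not given in the sources used here. The authors deposited whole-number counts of reads per gene, not normalized, with columns for unstranded, forward-strand and reverse-strand counting in a table for each sample, and 1 count table for the series. The series table equalled the reverse-strand column in all 16 samples when both were compared, and it was analysed as deposited. All 16 of its columns matched a sample by title, and 0 columns were left unmapped. Lines for unmapped, multimapping and unassigned reads stayed out of library sizes and tests. Unmapped reads made up 2.82% to 3.93% of a library, multimapping reads 9.23% to 15.0%, and reads outside annotated genes 21.8% to 35.0%.

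The reference at hand was GENCODE M21 on an older build, GRCm38. It supplied only gene names, biotypes, chromosomes and the order of neighbouring genes, matched by Ensembl identifier, so no coordinates are printed. It named 52081 of 55357 genes in the table. Terc itself is not analysed here, so neither its level nor the genotype of the libraries was checked against its reads. STAR's per-gene counts take only reads that align to 1 place, so a gene with a near-identical copy can lose reads to the copy or to the multimapping class. Values of such genes are therefore uncertain. Transcript sequences of pairs of copies were compared with blastn.

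Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups with a minimum count of 10, which left 14421 genes. Libraries were scaled by TMM, and a group-means model of all 16 libraries with 12 residual degrees of freedom was fitted with glmQLFit and tested with glmQLFTest. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. All tests are two-sided. Counts scaled to a common library size of 1e6 (CPM) use TMM-scaled library sizes, and log2 CPM values carry a prior count of 2. The comparisons were AUG with AUG_WT, del7 with del7_WT, the difference between those effects, and AUG_WT with del7_WT. Sharing between the mutants was measured as genes called in both and as a correlation across genes. Ratios of pooled counts carry 95% exact intervals, which cover counting error only.

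Gene lists were written from textbook liver biology, and 39 of 43 had enough measured members to be tested. The muscle, pancreas, adipose or gut, and sex-linked lists had 1, 1, 2 and 1 tested members. Lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, adjusted over the lists within a comparison. The level of a list in a library is the mean of its members' log2 CPM after each gene was centred on its mean. The design, the lists, the rule for named genes and the alternatives in processing were fixed before the data were examined, apart from additions stated below.

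The rule named genes with an adjusted p under 0.05 whose symbol is not a clone or pseudogene name and whose mutant libraries all lay on 1 side of the wild-type libraries, up to 10 in a direction by p. Where fewer than 5 passed, the 5 with the smallest p were given as values that did not pass. For the difference and for the wild types the rule took 5 in each direction without the separation requirement. It also allowed up to 4 members of each list that passed. The number followed through the alternatives was set at 2 members per list after results had been seen. Tes3-ps and Gm15772 fall outside the rule and were chosen after their values were seen.

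The pipeline was tested on simulated counts of all 14421 genes with 200 changed and another 30 shifted together as a list. Counts were drawn independently for each gene and without an outlying library, so the rates hold for that setting only. In the simulated AUG comparison it called 8.96% of 1.5-fold, 43.3% of 2-fold and 78.8% of 4-fold changes. For del7 it called 13.4%, 49.3% and 74.2%, and for the wild types 7.46%, 41.8% and 72.7%. False calls among 14191 unchanged genes were 0, 4 and 4.

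Alternatives tried were the unstranded column, RLE size factors, TMM without structural and mitochondrial RNA, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma voom with quality weights, and only the compared groups in the fit. The replicate number as a block, 1 surrogate variable from sva 3.50.0, all 8 wild types as control, a minimum fold of 1.2, an unadjusted p under 0.01, and each library left out were tried too. Chosen after seeing the data were the gene lists with each library left out, the del7 comparison without AUG_WT replicate 1, the lists without that library under an estimated correlation, and the correlation between the effects under all alternatives. A sex covariate was not run. All 16 libraries had Xist at 1559 to 2052 CPM. Exact permutation tests enumerated every relabelling of the libraries in R. Plots were drawn with matplotlib 3.10.9 in python 3.11.15.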

Results

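Liver RNA was sequenced from 4 groups of mice to ask how changes in Terc, the gene of the telomerase RNA, alter the liver transcriptome. Terc also encodes a small protein, TERP, linked to autophagy and cell stress. AUG and del7 are Terc mutants, and AUG_WT and del7_WT are the wild-type groups of their lines, with 4 samples each. The labels do not state that replicates are separate animals, so p-values measure the spread between these samples, which may be technical.

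Total gene counts ranged from 7714058 in del7 replicate 4 to 14629022 in del7_WT replicate 1. At this depth the median standard error of a log2 fold change was 0.22. No pair of libraries agreed within sampling noise, since the closest pair had a chi-square of 9.20 per gene, and all 16 were counted separately. Xist was high and Y-linked genes had at most 1 count in every library. Albumin, the main secreted protein of hepatocytes, took 4.37% to 11.5% of counts, and mitochondrially encoded genes 8.12% to 12.2%.

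AUG_WT replicate 1 stood apart from the other 15 libraries. On the first principal component, which held 34.5% of the variance, it lay at 126.1 and the others at 10.7 or below. It had the lowest albumin share, 4.37%, and the highest share of reads outside annotated genes, 35.0%. The B cell and plasma cell list was 4.18 higher in it than the mean of the other 3 AUG_WT libraries on the log2 scale, the T and natural killer cell list 3.40 higher, and the cell cycle list 2.85 higher. The list of fatty acid oxidation genes and targets of PPAR-alpha, the nuclear receptor that drives lipid burning, was -2.15 relative to them. AUG_WT replicate 2 lay at -53.0 on the second component, which held 12.4% of the variance.

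**Figure D1:**
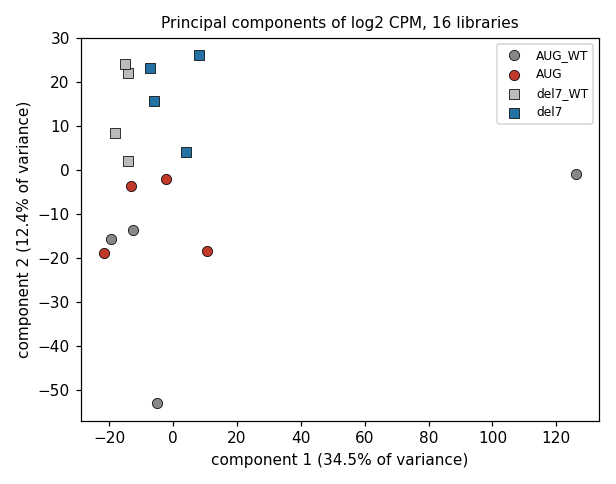
Each point is 1 of 16 libraries, placed by its first and second principal component of log2 CPM (34.5% and 12.4% of the variance), with colour and shape for the group. AUG_WT replicate 1 lies at 126.1 on the horizontal axis, apart from all others, and AUG_WT replicate 2 at -53.0 on the vertical axis.

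In AUG livers, 3 genes rose and 1 fell against AUG_WT among 14421 tested genes. Rps3a1 (ENSMUSG00000028081.7, chromosome 3), which encodes a protein of the small ribosomal subunit, fell from 94.1 ± 20.2 CPM to 16.7 ± 1.96 CPM (SD, n = 4), a log2 fold change of -2.50 (SE 0.16, edgeR adjusted p = 4.87e-07). Its near-identical copy Rps3a3 (ENSMUSG00000059751.8, chromosome 13), annotated as a processed pseudogene, rose from 0.161 ± 0.144 CPM to 46.5 ± 5.12 CPM, a log2 fold change of 7.99 (SE 0.45, edgeR adjusted p = 1.98e-07). The pooled counts of Rps3a3 were 2051 in AUG and 8 in AUG_WT. The transcripts of the copies match over 795 nucleotides with 9 mismatches (98.9% identity), so reads of either gene may be counted for the other and both values are uncertain.

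Hist1h2al (ENSMUSG00000091383.3, chromosome 13), a histone H2A gene annotated as a processed pseudogene, also rose, to 4.76 ± 1.73 CPM in AUG (SD, n = 4), with a log2 fold change of 7.16 (SE 0.73, edgeR adjusted p = 2.61e-04). It had 212 counts in AUG and 1 in AUG_WT, a ratio of 223 (95% exact interval 39.6 to 8861). Tes3-ps (ENSMUSG00000113255.2, chromosome 13), named after its values were seen, rose with 73 counts in AUG and 3 in AUG_WT, a ratio of 25.6 (95% exact interval 8.43 to 127; edgeR adjusted p = 0.0182). Similarity of these genes to others was not examined, so their counts are uncertain too. Tes3-ps did not pass with any 1 of AUG replicates 1, 3 and 4 or AUG_WT replicates 2, 3 and 4 left out, nor with the unstranded column, with the 2 groups alone, or with all 8 wild types as control, where its log2 fold change was 0.66.

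Next in order of p were genes that did not pass. Cd1d2, annotated as a polymorphic pseudogene, of the family that presents lipid antigens, had a log2 fold change of 2.96 (SE 0.50, edgeR adjusted p = 0.0791). Over the alternatives this gene was at an adjusted p of 3.72e-04 to 0.581. It passed without AUG_WT replicate 4 (0.0480), by DESeq2 and with all 8 wild types as control. B3galnt1, a glycosyltransferase of glycolipid synthesis, had 2.33 (SE 0.46) and Asic5, an ion channel of the acid-sensing family, 2.17 (SE 0.43), both at an adjusted p of 0.293. By DESeq2 both passed (0.00274 and 8.74e-04), and Asic5 passed by limma voom (0.0383). Below 0 lay Scnm1 (-0.62), a splicing factor, Mpped2 (-1.59) and Ppp1r10 (-0.71), a protein phosphatase subunit, each at an adjusted p of 0.561. Cd1d2, B3galnt1, Asic5, Scnm1 and Rps3a1 all lie on chromosome 3, which also carries Terc. An unadjusted p under 0.05 was reached by 1270 genes, 207 higher and 1063 lower, where 721 are given by chance. Between AUG and AUG_WT, 296 genes (2.05%) had groups that did not overlap, against a chance share of 2.86%.

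**Figure D2:**
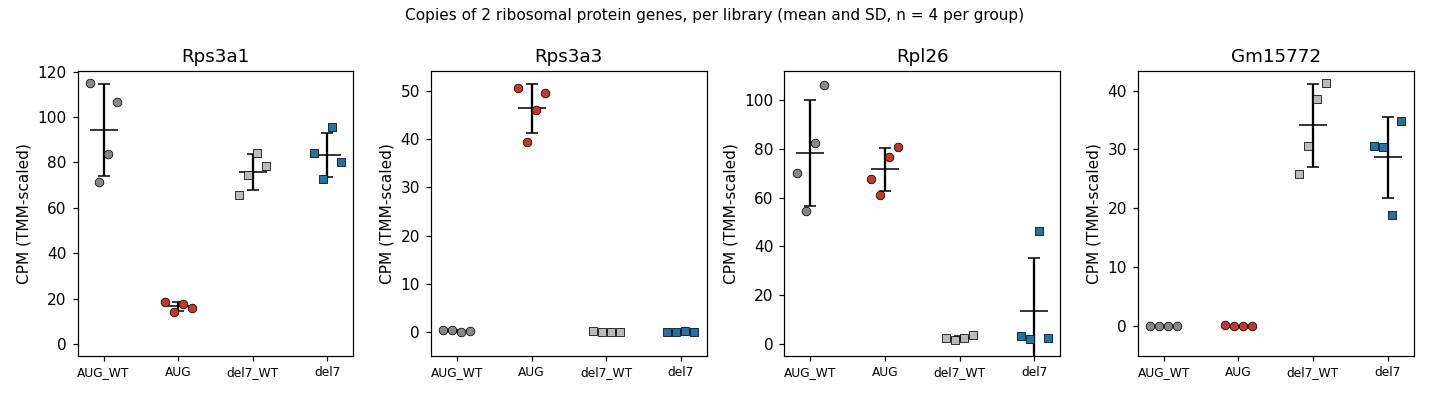
CPM of Rps3a1, Rps3a3, Rpl26 and Gm15772 in each library (points) by group, with the mean and SD of 4 libraries (bars). AUG libraries have low Rps3a1 (16.7 ± 1.96 CPM) and high Rps3a3 (46.5 ± 5.12 CPM), and Rpl26 and Gm15772 divide the AUG line from the del7 line, apart from del7 replicate 3 at 46.2 CPM of Rpl26.

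By gene list, lymphoid and proliferation markers ranked lower in AUG than in AUG_WT and some metabolic lists ranked higher, with 7 lists higher and 10 lower by camera at the preset correlation. Each of these 17 had an adjusted p of 0.948 with an estimated correlation, and 0 lists passed by fry. AUG_WT replicate 1 moves with nearly all of them. Without it, 2 lists ranked higher and 5 lower, and of the original 17 only the erythroid list (adjusted p = 8.76e-07, and 0.870 with an estimated correlation) passed in its original direction. The 5 lower lists also held fatty acid oxidation genes, which had ranked higher, and others that had not passed with all libraries. With an estimated correlation, 0 lists passed in either direction without that library.

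Of 16 B cell and plasma cell markers, 15 were lower in AUG, with a median log2 fold change of -2.57 (camera adjusted p = 7.58e-05). Ighm, the constant region of IgM, had -2.51 (SE 0.71), with 36.6 ± 7.49 CPM in AUG and 209 ± 187 CPM in AUG_WT (SD, n = 4). Adjusted over the list alone, 13 members passed, against 0 over all genes. T and natural killer cell markers had a median of -1.72 (0.0331), with 12 of 13 lower and 0 passing over the list alone. All 20 cell cycle genes were lower, with a median of -1.39 (2.77e-05), and Mki67, a marker of dividing cells, had -3.51 (SE 0.95), the 1 member that passed over the list alone. Replication-dependent histone genes had a median of -1.04 (0.022), with all 10 lower and Hist2h2ac (-1.21, SE 0.33) passing over the list alone. Interferon-stimulated genes had -0.45 (0.00178), fibrosis and extracellular matrix genes -0.41 (0.00225) and immediate early genes -0.32 (0.0373). In AUG_WT replicate 1 these lists were above the other AUG_WT libraries, interferon by 1.22 and fibrosis by 1.23. Without it, B cell markers were at an adjusted p of 0.656, T and natural killer markers at 0.167, cell cycle genes at 0.875, histone genes at 0.624, interferon genes at 0.938, fibrosis genes at 0.938 and immediate early genes at 0.686. T and natural killer markers also did not pass without AUG replicate 1 or 4, interferon genes without AUG replicate 1, fibrosis and histone genes without AUG replicate 4, and immediate early genes without AUG replicates 1, 2 or 3 or AUG_WT replicate 4.

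Erythroid markers, the genes of red cells and their precursors, had a median of -1.84 in AUG (camera adjusted p = 0.00114), with 8 of 9 lower. Bpgm, which makes the red cell metabolite 2,3-bisphosphoglycerate, had -1.14 (SE 0.35), and the globin Hbb-bt had -2.48 (SE 0.77). Adjusted over the list alone 3 members passed, against 0 over all genes. AUG_WT replicate 1 was -1.58 relative to the other AUG_WT libraries for this list, and the list did not pass without AUG_WT replicate 4 (adjusted p = 0.0966). Cholangiocyte markers, of the bile duct lining, had a median of -0.86 (0.00553), with Epcam at -1.79 (SE 0.53) the 1 member passing over the list alone. Cytosolic ribosomal protein genes were slightly lower, by a median of -0.22 (7.36e-06), in 38 of 39. Without AUG_WT replicate 1 the cholangiocyte list had an adjusted p of 0.115 and the ribosomal list 0.134.

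Higher in AUG were nuclear genes of oxidative phosphorylation, by a median of 0.16 in 29 of 30 (camera adjusted p = 4.30e-06), and genes of bile acid synthesis and transport, by 0.28 in 18 of 21 (2.77e-05). Fgfr4, the hepatocyte receptor that restrains bile acid synthesis, had 0.44 (SE 0.13). Fatty acid oxidation genes had a median of 0.14 (0.00591), unfolded protein response genes 0.20 (0.0373), xenobiotic metabolism genes 0.17 (0.0331), periportal markers 0.11 (0.022) and endothelial markers 0.12 (0.0373). No member of these lists passed over the list alone. Without AUG_WT replicate 1, fatty acid oxidation genes turned lower (camera adjusted p = 0.0404), but 0 lists were lower with an estimated correlation. At the preset correlation, without that library, oxidative phosphorylation was at 0.914 and bile acid genes at 0.654. Periportal markers were at 0.938, xenobiotic genes at 0.718, endothelial markers at 0.700 and unfolded protein response genes at 0.349. Fatty acid oxidation did not pass without AUG replicate 4 (0.0955), nor xenobiotic genes without AUG replicates 1 or 4 or AUG_WT replicate 2, nor endothelial markers without AUG replicate 2 or AUG_WT replicate 4. Unfolded protein response genes did not pass without AUG replicates 1 (0.973) or 3 or AUG_WT replicates 3 or 4. Without AUG_WT replicate 1, inflammatory cytokine and NF-kB genes (9.37e-04) and Kupffer cell markers (0.0460) ranked higher, at adjusted p-values of 0.870 and 0.975 with an estimated correlation.

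The del7 comparison had 0 genes past the threshold by edgeR, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 277 genes, 170 higher and 107 lower, where 721 are given by chance. These counts depend on libraries outside the comparison, which share the estimate of spread: at an unadjusted p under 0.01, del7 had 22 genes higher and 18 lower, but 113 and 52 without AUG_WT replicate 1 and 206 and 75 with the 2 groups alone. Limma voom called 0, and DESeq2 called 1, Tmc5, which was seen only afterwards and had 0 counts in all del7 libraries and 31, 0, 1 and 1 in del7_WT. Between del7 and del7_WT, 579 genes (4.01%) had groups that did not overlap, against a chance share of 2.86%. The genes with the smallest p, none of which passed, included several of myeloid cells. Vsig4, a complement receptor of Kupffer cells, had 44.7 ± 10.4 CPM in del7 and 24.1 ± 3.59 CPM in del7_WT (SD, n = 4), a log2 fold change of 0.89 (SE 0.24). Adgre4, an adhesion receptor of macrophages, had 1.10 (SE 0.27), Cd300a, an inhibitory receptor of leukocytes, 0.96 (SE 0.25), Nfam1, an immune receptor, 1.08 (SE 0.31), and Noxred1 1.64 (SE 0.47). Mfap4, a protein of elastic fibres, had -1.71 (SE 0.36), Zfp157 -0.63, Sntg2 -1.15, Cphx1 -0.80 and Cpxm2 -1.14.

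Macrophage and inflammatory genes ranked higher in del7 and female-biased liver genes lower, among 5 lists higher and 2 lower by camera at the preset correlation. All 7 had an adjusted p of 0.929 with an estimated correlation, and 0 passed by fry. Kupffer cell and macrophage markers had a median log2 fold change of 0.73 (camera adjusted p = 7.79e-15), with 17 of 18 higher. Adjusted over the list alone 1 member, Vsig4, passed (0.0334), against 0 over all genes, and Ms4a7, a macrophage membrane protein, had 1.69 (SE 0.68). Inflammatory cytokine and NF-kB genes had a median of 0.48 (1.29e-04) with 15 of 16 higher, among them the chemokine Ccl2 at 0.93 (SE 0.47) and the inflammasome sensor Nlrp3 at 0.71 (SE 0.46). Both lists passed with each of 9 libraries left out, at adjusted p-values up to 1.48e-09 and 0.00295. AUG_WT replicate 1 is in neither group, and without it the Kupffer list had a camera adjusted p of 3.55e-17 at the preset correlation. With an estimated correlation, 0 lists were higher and 0 lower in del7 without that library.

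Female-biased liver genes, which sex hormones and growth hormone pulses regulate, had a median of -0.41 in del7 (camera adjusted p = 1.08e-04), with 18 of 22 lower. Cyp3a44, a cytochrome P450, had -1.67 (SE 0.77), and the list passed with each of 9 libraries left out, at up to 0.0126. Its levels overlapped widely between the groups, however. They were -0.693, 0.488, -0.774 and 0.065 in del7 replicates 1 to 4, and -0.155, 0.606, 0.002 and 0.713 in del7_WT. In both groups replicates 1 and 3 lay below replicates 2 and 4. Erythroid markers had a median of 0.89 (7.52e-04) in 9 of 9, with the red cell anion exchanger Slc4a1 at 2.94 (SE 0.94). Neutrophil markers had 1.18 (0.00725) in 6 of 6, with Csf3r, the G-CSF receptor, at 1.06 (SE 0.44) and the calgranulin S100a9 at 1.67 (SE 0.92). Without del7 replicate 2 these lists were lost, at adjusted p-values of 0.212 and 0.203. Cytosolic ribosomal protein genes had a median of 0.08 (0.0103) and mitochondrially encoded genes -0.26 (0.0196), in 7 of 7, with mt-Nd6, a complex I subunit, at -0.34 (SE 0.24). The ribosomal list was lost without del7_WT replicate 1 (0.951), del7_WT replicate 2 or del7 replicate 3, and the mitochondrial list without del7 replicate 3 (0.235), del7 replicate 4 or del7_WT replicate 4. Of these lists, 0 had a member passing over the list alone, whereas 2 members of the male-biased list passed that way, lower, although the list did not pass (0.761) and its median was 0.13 with a mean of -0.29.

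**Figure D3:**
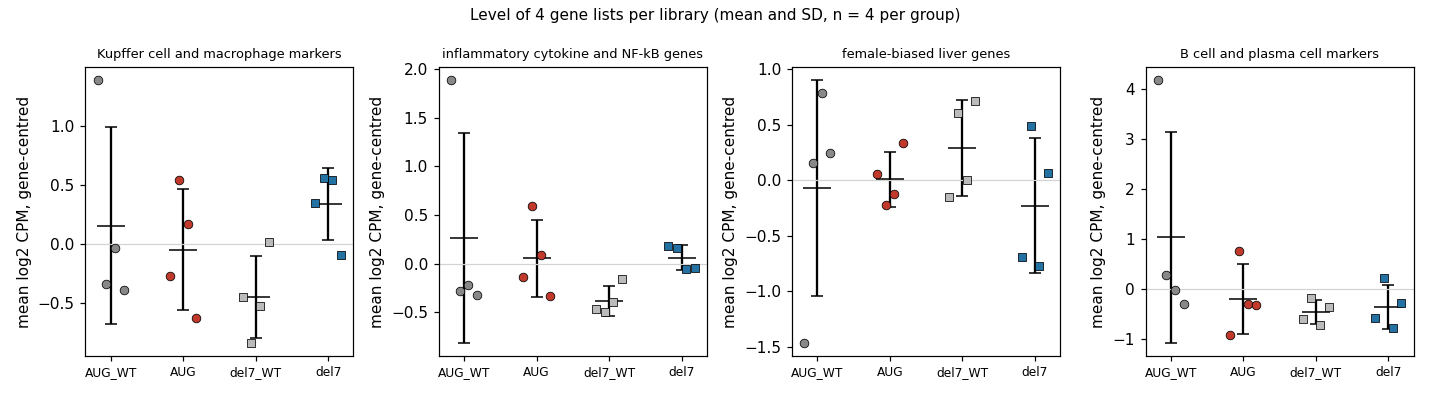
Level of 4 gene lists in each library (points, mean log2 CPM of the members after centring each gene), by group, with the mean and SD of 4 libraries (bars). Kupffer markers lie between -0.095 and 0.555 in del7 and between -0.831 and 0.014 in del7_WT, and AUG_WT replicate 1 lies at 4.167 for B cell markers.

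With all libraries, lists for what is known of TERP did not pass in either mutant. Autophagy and lysosome genes had a median log2 fold change of 0.03 in AUG (camera adjusted p = 0.314) and -0.05 in del7 (0.497). AUG_WT replicate 1 lay at -0.355 for this list, below all other libraries. The rest of AUG_WT lay at 0.076 to 0.176 and AUG at 0 to 0.079. In AUG the list passed in the direction of the full fit in 1 of 8 fits with 1 library left out. It turned direction in 1 fit, and a pass in the opposite direction was not counted. AMPK and mTOR signalling genes, which couple growth to energy supply, had -0.05 in both (0.817 in AUG and 0.251 in del7). Telomerase and telomere genes had -0.02 in AUG (0.943) and -0.05 in del7 (0.739), although camera ranked them higher in both. Neighbours of Terc had -0.01 in AUG (0.817) and -0.04 in del7 (0.739). p53 target genes had -0.18 (0.495) and -0.01 (0.796), heat shock genes 0.22 (0.0901) and 0.09 (0.739), ATF4 target genes -0.02 (0.817) and 0.10 (0.616), and NRF2 genes 0.03 (0.817) and -0.06 (0.739). Among metabolic lists, fatty acid synthesis had 0.0040 in AUG (0.595) and -0.05 in del7 (0.375), cholesterol synthesis 0.08 (0.735) and 0.09 (0.343), gluconeogenesis and glycogen 0.02 (0.437) and 0.01 (0.832), and the insulin-like growth factor list -0.11 (0.878) and -0.04 (0.126). Pericentral markers had 0.07 (0.145) and -0.12 (0.739), circadian genes -0.01 (0.595) and -0.02 (0.739), acute phase genes -0.06 (0.858) and 0.18 (0.0633), and stellate cell markers -0.0039 (0.817) and -0.04 (0.427). With 1 library left out, some of these passed in the direction of the full fit. In AUG, heat shock genes did in 3 of 8 fits, pericentral markers in 2, and fatty acid synthesis, cholesterol synthesis, gluconeogenesis and growth factor lists in 1 each. In del7, cholesterol synthesis and acute phase genes did in 3 of 9 fits, the growth factor list in 2, and circadian and heat shock genes in 1 each.

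The lists not given so far had these values where they did not pass. In AUG, inflammatory genes had a median of -0.43 (camera adjusted p = 0.171), Kupffer markers -0.42 (0.254), male-biased genes 0.10 (0.261), female-biased genes 0.02 (0.749), mitochondrially encoded genes -0.06 (0.516) and neutrophil markers -0.39 (0.977). In del7, fibrosis genes had -0.19 (0.0879), bile acid genes -0.13 (0.150), oxidative phosphorylation genes -0.07 (0.150), endothelial markers 0.05 (0.150), unfolded protein response genes -0.07 (0.193), T and natural killer markers 0.38 (0.210), immediate early genes 0.15 (0.251) and fatty acid oxidation genes -0.09 (0.391). Histone genes had -0.06 (0.480), xenobiotic genes -0.12 (0.586), cell cycle genes 0.05 (0.739), periportal markers -0.03 (0.739), interferon genes -0.0045 (0.761), cholangiocyte markers -0.02 (0.761) and B cell markers 0.33 (0.761). With 1 library left out, in the direction of the full fit, inflammatory genes passed in AUG in 3 of 8 fits, Kupffer markers in 2 and mitochondrially encoded genes in 1. In del7, fibrosis, endothelial and unfolded protein response lists passed in 3 of 9 fits each, oxidative phosphorylation genes in 2 and fatty acid oxidation genes in 1. Camera ranked lists higher in AUG although the median was below 0 for telomere, neighbour, circadian, ATF4, growth factor, mitochondrial and neutrophil genes, and although the mean was below 0 for autophagy, gluconeogenesis, fatty acid synthesis, NRF2 and sex-biased genes. In del7 the sign of the test and the median differed for telomere, ATF4, gluconeogenesis, cholangiocyte and male-biased genes, and the median and mean for NRF2, circadian and p53 genes.

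Whether the mutants differ in effect was tested directly. Of 14421 genes, 1 had a different effect, Rps3a1, which encodes the small-subunit ribosomal protein and was 83.1 ± 9.67 CPM in del7 and 75.8 ± 7.86 CPM in del7_WT (SD, n = 4). The difference between the AUG and del7 effects was -2.63 on the log2 scale (SE 0.21, edgeR adjusted p = 3.47e-05). Cd1d2 (4.79, adjusted p = 0.196, but 0.00381 by DESeq2), Asic5 (2.89, but 0.00710 by DESeq2), Acer3 (1.15), a ceramidase, Crym (3.34), a thyroid hormone binding protein, and Zfp157 (0.81) did not pass by edgeR. Neither did Noxred1 (-3.04), Cdr2 (-2.08), Ehbp1l1 (-1.37) and Bahd1 (-0.72), a chromatin silencing factor, which were at an adjusted p of 0.864. Rps3a3 had 7.23 (SE 2.60, edgeR adjusted p = 0.864), with 1 count in del7_WT and 2 in del7, but passed by DESeq2 (0.00381) and limma voom (3.36e-04). Tes3-ps passed by both (0.00381 and 0.0179) and without AUG_WT replicate 1 (0.0301), and Tmc5 by DESeq2 (0.00105). At an unadjusted p under 0.05 there were 751 genes.

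Of the lists, 8 ranked higher and 10 lower in this difference by camera, and all 18 were at an adjusted p of 0.78 with an estimated correlation. Kupffer markers had a median of -1.04 (1.59e-07) with 18 of 18 negative, cytosolic ribosomal protein genes -0.26 (2.69e-07) with 39 of 39, and erythroid markers -2.81 (5.65e-06) with 9 of 9. Adjusted over the list alone, 7 erythroid members passed, against 0 over all genes. Without AUG_WT replicate 1 these were the 3 lists that passed, at 1.62e-05, 0.00222 and 1.36e-11, and at 0.950, 0.950 and 0.388 with an estimated correlation. Oxidative phosphorylation (0.25, 2.19e-06) and bile acid genes (0.34, 1.27e-05) were higher in the full fit. The female-biased list ranked higher (0.00778) with a median of 0.26 and a mean of -0.05. Cell cycle, B cell, T cell, inflammatory, cholangiocyte, immediate early and interferon lists ranked lower, and fatty acid oxidation, unfolded protein response, xenobiotic, mitochondrial and periportal lists higher, none of which passed without that library.

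Since del7 had 0 called genes, none could be shared at the threshold. At an unadjusted p under 0.01, 28 genes were higher in AUG and 22 in del7, and 1 was in both, B3galnt1, against 0.0427 for independent lists (Fisher's exact p = 0.0419). For lower genes, 185 and 18 shared 0, against 0.231. Without AUG_WT replicate 1 there were 59 higher and 130 lower in AUG and 113 and 52 in del7, with 2 shared higher and 3 shared lower. Leaving out others moved these counts too: AUG had 106 higher and 576 lower without AUG_WT replicate 4, 70 and 504 without AUG_WT replicate 3, 46 and 371 without AUG_WT replicate 2, and 81 lower without AUG replicate 1. In del7, 10 were higher and 9 lower without del7 replicate 1, 11 higher without del7_WT replicate 2 and 33 higher without del7 replicate 4. The comparisons share no control libraries. Across genes, which are not independent replicates, the fold changes correlated at r = -0.129. On log2 CPM means r was -0.118 with a covariance of -0.0129, and exact permutation of labels within lines, over 4900 relabellings, gave p = 0.465 and a mean covariance of 0. Without AUG_WT replicate 1 the correlation turned to 0.193.

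The wild-type groups, which measure how the mouse lines differ without the mutation, differed at 5 genes, 1 higher and 4 lower in AUG_WT. The count depends on the tool, with 42 higher and 28 lower by DESeq2 and 5 and 7 by limma voom, and without AUG_WT replicate 1 it was 3 and 7. Ntrk2 (ENSMUSG00000055254.16), the receptor of brain-derived neurotrophic factor, rose to 33.0 ± 19.4 CPM from 2.30 ± 1.03 CPM (SD, n = 4; log2 fold change 3.86, SE 0.59, edgeR adjusted p = 0.0380). Zfp157 (ENSMUSG00000036898.17), a zinc finger gene, fell to 9.17 ± 1.19 from 18.4 ± 3.08 CPM (-1.01, SE 0.16, 0.0380), and Rtn4rl1 (ENSMUSG00000045287.7), a Nogo receptor relative, fell by a log2 fold change of -1.22 (SE 0.20, 0.0446). Gm15772 (ENSMUSG00000062353.7), a processed pseudogene named after its values were seen, had 1457 counts in del7_WT and 2 in AUG_WT, a ratio of 765 (95% exact interval 211 to 6323; edgeR adjusted p = 9.53e-08). Tes3-ps, also named afterwards, had 85 and 3 counts, a ratio of 29.8 (95% exact interval 9.84 to 147; edgeR adjusted p = 0.0147). Gm15772 passed with each of 8 libraries left out. The others did not: Rtn4rl1 was lost with each one left out, Ntrk2 with any but AUG_WT replicates 1 and 3, Zfp157 with any but del7_WT replicate 3 and AUG_WT replicates 1 and 3, and Tes3-ps without del7_WT replicate 2 or AUG_WT replicates 2 or 4.

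Rpl26, a large-subunit ribosomal protein gene whose near-identical copy is Gm15772, had 78.3 ± 21.9 CPM in AUG_WT and 2.36 ± 0.828 CPM in del7_WT (SD, n = 4) but did not pass (log2 fold change 5.05, SE 0.88, edgeR adjusted p = 0.0777). The groups did not overlap, at 54.4 to 106 CPM and 1.39 to 3.40 CPM. All 4 groups share the estimate of spread, and del7, outside this comparison, had 13.3 ± 21.9 CPM, with replicate 3 at 46.2 CPM. The transcripts match over 438 nucleotides with 2 mismatches (99.5% identity), so both values are uncertain. H2-Q2, a class I histocompatibility gene of a family with similar copies, had 5.22 (0.109), Crybg2 2.61 (0.139) and Setbp1 1.19 (0.189). Cyp46a1, which hydroxylates cholesterol, had -5.11 (0.107), with 6.25 ± 4.72 CPM in AUG_WT and 213 ± 96.5 CPM in del7_WT, Plxnb1, a semaphorin receptor, -0.77 (0.0777), and Kif5a, a kinesin, -1.48 (0.109). At an unadjusted p under 0.05 there were 1701 genes, 1331 higher and 370 lower. Groups did not overlap for 509 genes (3.53%), against 2.86% by chance.

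Immune and proliferation lists ranked higher in AUG_WT than in del7_WT, among 11 higher and 8 lower by camera, with adjusted p-values from 0.679 to 0.79 with an estimated correlation. B cell markers had a median of 3.33 (camera adjusted p = 5.35e-05), T and natural killer markers 2.54 (6.28e-04), cell cycle genes 1.73 (1.24e-05) and Kupffer markers 0.82 (1.86e-05). Adjusted over the list alone 14, 9, 13 and 5 members passed, against 0 over all genes. Interferon (0.67), inflammatory (0.91), immediate early (0.76, 1 over the list alone), erythroid (1.68), neutrophil (1.52), histone (1.13) and ribosomal lists (0.25) were also higher. Bile acid genes (-0.28, 4.21e-05; 1 over the list alone), unfolded protein response (-0.27, 0.00165), heat shock (-0.22, 0.0298), periportal (-0.13), stellate (-0.15), cholangiocyte (-0.26), oxidative phosphorylation (-0.08) and insulin-like growth factor lists (-0.08) were lower. AUG_WT replicate 1, high in the lymphoid lists, is in this comparison. Without it 8 lists ranked higher and 4 lower. T cell markers were at 0.292, cell cycle genes at 0.426, interferon genes at 0.127, inflammatory genes at 0.620, neutrophil markers at 0.425, histone genes at 0.635, bile acid genes at 0.386 and periportal markers at 0.859. Oxidative phosphorylation turned higher (0.00153), and B cell markers (0.0268), Kupffer markers (0.0335) and ribosomal genes (0.0167) still passed. With an estimated correlation, 0 lists passed in either direction without that library. Erythroid markers were lost without AUG_WT replicate 4, unfolded protein response genes without del7_WT replicate 3, and the heat shock, stellate, cholangiocyte and growth factor lists without any 1 of 3 libraries or more.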

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

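The tests of AUG_WT replicate 1 and of the Kupffer list over other splits were chosen after the results were seen, and the other counts over splits were planned. A sample was noted when its gap to the nearest of its group took up most of the group's range. Of 196 groups of values tested this way, 16 met it, where 9.80 are given by chance. Of these 16, AUG_WT replicate 1 holds most. Its reads outside annotated genes were 34.97%, its first component 126.1, and its list levels were 2.706 for cell cycle, -1.785 for fatty acid oxidation, -1.298 for bile acid, 1.884 for inflammatory, 0.999 for fibrosis, -0.695 for pericentral, 3.149 for T and natural killer, 4.167 for B cell and 2.097 for neutrophil genes.

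The B cell, T cell and cell cycle lists were higher in AUG_WT replicate 1 than in any other library, although Ighm was also high in AUG_WT replicate 2 (319 CPM) and del7 replicate 2 (134 CPM). Low depth is argued against by its total of 10569373 counts (10.6 M), more than AUG_WT replicate 3 had. A lower share of hepatocyte RNA that raises every other cell type alike is argued against by endothelial markers, which were -0.31 relative to the other 3 AUG_WT libraries while B cell markers were 4.18 above them. Lymphoid tissue or an infiltrate in the piece of liver stays open as a possible source: Cd74 (1469 CPM), Ptprc (512 CPM), Ighm (415 CPM) and Cd79a (31.7 CPM) were highest there among 16 libraries, 4 of 4, but were picked after the B cell list was seen to be high in it, which decides nothing. No biological explanation from the design was tested because the sample is a wild type like 3 others.

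Other samples that met this rule were AUG replicate 2 for neighbours of Terc (-0.083), AUG replicate 4 for autophagy genes (0.079), AUG replicate 1 for fatty acid synthesis (0.229), AUG_WT replicate 3 for heat shock genes (0.027) and del7 replicate 3 for circadian genes (0.364). By the test of the difference itself, the AUG and del7 effects differed for Rps3a1 (-2.63) and for 18 lists at the preset correlation. The forward-strand counts, which no comparison above uses, hold reads from the strand opposite to the annotated gene. The CPM of these reads is scaled to forward-strand counts alone, which were 3.16 to 3.77 per 100 reverse-strand counts. It is therefore not on the scale of CPM elsewhere in the text. Reads opposite to Pomp were higher in AUG than in AUG_WT (log2 fold change 4.92, edgeR adjusted p = 4.10e-05), with 191 to 378 such CPM in AUG and 3.47 to 12.6 in AUG_WT. Those opposite to Snhg12 (-5.92, edgeR adjusted p = 5.86e-04) and Sh2b2 (-4.26, 0.00166) were lower in AUG_WT than in del7_WT, and the reverse-strand counts called none of these genes.

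For AUG, 3 of the 35 splits of its 8 libraries called 4 genes or more, the real split with 4 included and 7 the highest of the others, so chance cannot be excluded for that count. For del7 the count was 0 in the real split and 0 in the highest other, and all 35 splits reach 0 whatever the data, so this decides nothing. For the difference, 14 of 100 splits gave 1 or more, with 1 in the real and 2 the highest other. Besides the real one, some of these splits kept the real AUG and AUG_WT labels and relabelled only the del7 line, so they carry the AUG change. Chance cannot be excluded for that count, which does not weigh how far its gene, Rps3a1, changed (edgeR adjusted p = 3.47e-05). For the wild types, 1 of 35 splits gave 5 or more, the real one, with 2 the highest other. This argues against chance for that count but does not exclude it. It is the smallest share that 35 splits can give, and it was not adjusted for the other counts over splits. For lists, chance cannot be excluded in any comparison: 25 of 35 splits reached the 17 lists of AUG (highest other 28), 25 of 35 the 7 of del7 (22), 43 of 100 the 18 of the difference (28) and 21 of 35 the 19 of the wild types (26). The Kupffer list in del7 had a -log10 p of 15.7, and 2 of 35 splits were as large, with 18.2 the highest other, so chance cannot be excluded.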

How the results depend on the processing

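The gene lists with each library left out, the lists without AUG_WT replicate 1 under an estimated correlation, the del7 comparison without that library and the correlation between effects under all alternatives were chosen after the data were seen, and the other alternatives were planned. The cause of a change was not tested unless stated. Rps3a3 (7.70 to 8.89), Rps3a1 (-2.60 to -2.35) and Hist1h2al (5.81 to 8.76) passed in AUG under every alternative run, as did Rps3a1 in the difference (-2.73 to -2.49) and Gm15772 in the wild types (-9.82 to -8.09). Over the single genes named in AUG and all alternatives, 864 values kept direction and side of the threshold, 7 newly passed, 10 no longer passed and 8 reversed. For del7 these were 474, 0, 0 and 2, for the difference 1138, 3, 0 and 3, and for the wild types 838, 20, 33 and 5.

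With DESeq2, AUG had 6 genes higher and 3 lower, del7 1 lower, the difference 5 higher, and the wild types 42 higher and 28 lower. With limma voom, AUG had 5 higher, the difference 2 higher, and the wild types 5 higher and 7 lower. The wild types had 5 higher with no filter, 8 higher with the compared groups alone, 3 higher with 1 surrogate variable, and 2 lower with the unstranded column. At an unadjusted p under 0.01, 1 gene was higher in both mutants.

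Replicate numbers 1 to 4 are shared by the groups' titles, while another label numbers the AUG_WT samples 5 to 8, so same numbers in AUG and AUG_WT may mean nothing. The labels do not say that a number marks a shared animal, litter or batch, and not every same-numbered pair deviated together, so the samples were not treated as paired. Deviations of same-numbered samples correlated at -0.117, -0.0923, -0.157 and 0.351 in AUG and AUG_WT, and at 0.176, 0.275, 0.283 and 0.0919 in del7 and del7_WT. Not every sample correlated best with its own number: numbers 1, 2 and 3 did both ways in del7 and del7_WT, and number 4 alone in AUG and AUG_WT, a hint from the data and not from the design. With the replicate number as a block, the difference had 1 gene higher, and the wild types 0 higher and 1 lower. With the block AUG had 3 higher and 1 lower, with Cd1d2 (edgeR adjusted p = 0.00901) called and Tes3-ps not called, and del7 had 0 and 0. Cd1d2 was the gene higher in the difference (edgeR adjusted p = 0.0325).

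The correlation of the effects, -0.129, became 0.125 with voom, 0.0979 with 1 surrogate variable and 0.464 with all 8 wild types, where both comparisons share controls, and ranged from -0.275 to 0.193 with 1 library left out. Among list members, Cxcl10 in AUG (-1.56) became 0.45 with voom and 0.28 with the surrogate variable, and in the difference (-1.87) 0.0921 and 0.35. Cdh1 in AUG (-1.54) became 0.26 with voom. Ndufs1 in the wild types (-0.18) became 0.0098 with voom and 0.0044 with the surrogate variable, where Hist1h1d (1.82) became -0.0918. With all 8 wild types as control, Rpl13 and Rpl18 in del7 became -0.0099 and -0.017.

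With 1 library left out, genes lower in AUG ranged from 1 to 2, genes higher in the difference from 0 to 1, and in the wild types genes higher from 0 to 5 and lower from 1 to 7. Single genes reversed mostly without AUG_WT replicate 1. In AUG without it, Cxcl10 was 0.50, Trac 0.17 (from -2.55), Btg2 0.0506 (from -1.16) and Hist1h2bb 0.0921 (from -1.60). Cxcl10 in the difference was 0.20 without it, and Hist1h1d in the wild types -0.0647. Cdh1 in AUG was 1.25 without AUG_WT replicate 2, and Krt7 in the wild types (-0.52) 0.20 without del7_WT replicate 4. At the other end, in AUG against AUG_WT, Cxcl10 was -1.92 and Trac -3.11 without AUG replicate 2, Cdh1 -2.47 without AUG replicate 3, Btg2 -1.41 without AUG_WT replicate 3 and Hist1h2bb -1.92 without AUG_WT replicate 2. In the difference between the AUG and del7 effects, Cxcl10 was -2.23 without AUG replicate 2. In AUG_WT against del7_WT, Hist1h1d was 2.12 without AUG_WT replicate 3 and Krt7 -0.73 without AUG_WT replicate 1. Lists higher ranged from 2 to 10 in AUG, 3 to 8 in del7 and 0 to 9 in the difference. Lists lower ranged from 5 to 12 in AUG, 1 to 5 in del7, 3 to 13 in the difference and 4 to 13 in the wild types. With an estimated correlation, with fry, and with an estimated correlation without AUG_WT replicate 1, 0 lists were higher and 0 lower in each of the 4 comparisons, against 7 and 10, 5 and 2, 8 and 10, and 11 and 8 with camera at the preset value. The sex covariate and the alternatives for Terc were not run, and leaving out uncompared groups changes nothing for the difference, which uses all 4.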

Other observations

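All tests in this part were chosen after the results were seen. Stress genes spread widely within groups. Replicates 1 and 3 were each higher than replicates 2 and 4 in AUG, del7 and del7_WT, without a test of why. AUG_WT did not show this order for unfolded protein response genes. Unfolded protein response genes, the chaperones of the endoplasmic reticulum, lay at 0.707, -0.352, 0.068 and -0.465 in AUG replicates 1 to 4, at 0.848, -0.594, 0.428 and -0.609 in del7, at 0.288, -0.462, 0.765 and 0.005 in del7_WT, and at -0.179, 0.156, -0.214 and -0.390 in AUG_WT. Heat shock genes lay at 0.654, -0.485, 0.190 and -0.349 in AUG, at 0.750, -0.529, 0.747 and -0.473 in del7, at 0.365, -0.545, 0.510 and -0.059 in del7_WT, and at -0.256, -0.272, 0.027 and -0.274 in AUG_WT.

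Genes on chromosome 3 were frequent among the smallest p-values of AUG against AUG_WT, with 7 of 15 genes at a p under 0.001 there, where 766 of the tested genes lie (Fisher's exact p = 5.23e-06, named genes included). Chromosome 13 followed with 3 of 557, which were Rps3a3, Hist1h2al and Tes3-ps. With the named genes left out, 16 of 761 on chromosome 3 had a p under 0.01 against 1.37% elsewhere (Fisher's exact p = 0.110, and 0.0381 without AUG_WT replicate 1). In del7, with all genes kept, 6 of 766 did against 0.250% (Fisher's exact p = 0.0183). Between the wild types the share on chromosome 3 was lower than elsewhere, 2.09% against 3.42% (Fisher's exact p = 0.0490). That the mutation itself lowers Rps3a1 whichever allele carries it is argued against by the difference between the effects, -2.63. For the 4 other named genes on chromosome 3, taken as a set, such an effect stays open. B3galnt1 moved in the same direction in del7 (1.55, SE 0.44, edgeR unadjusted p = 0.00295). Cd1d2 moved in the opposite direction (-1.83, SE 0.68, edgeR unadjusted p = 0.0168), on 19 counts in del7_WT and 5 in del7. Asic5 had -0.72 (SE 0.44) and Scnm1 -0.05 (SE 0.14). A segment of another strain carried along with the edited Terc may be the source. With named genes left out, the 200 tested genes nearest Terc gave 6 of 199 at a p under 0.01 (3.02%) against 1.38% elsewhere (Fisher's exact p = 0.0622), which leaves it open. With named genes included, 3 of 200 there had a p under 0.001 (Fisher's exact p = 0.00107). They were Scnm1, which helped prompt the test, and Gm20633 and 6330549D23Rik, which the naming rule bars. That count leaves the segment open too, since it was chosen after the p-values were seen. Rps3a1, Cd1d2, Asic5 and B3galnt1 lie 170 to 213 tested genes from Terc, outside this set, so neither count covers them. A trade of reads between Rps3a1 and Rps3a3 also stays open, since their summed CPM still differed by -0.56 on the log2 scale, less than Rps3a1 alone. The sums were 63.1 ± 6.74 in AUG and 94.3 ± 20.2 in AUG_WT (SD, n = 4, exact permutation p = 0.0286, the smallest possible). An effect of the AUG allele alone stays open too. No other line carries that allele, so it cannot be told apart from sequence inherited with it.

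Rpl26 and its copy Gm15772 mirrored each other between the lines. Rpl26 was 54.4 to 106 CPM in AUG_WT and 1.39 to 3.40 CPM in del7_WT, and Gm15772 at most 0.178 CPM in the AUG line and 25.8 to 41.2 CPM in del7_WT. A trade of reads between the copies, for example through a strain variant that makes Rpl26 reads align better to Gm15772, might account for this, but the summed CPM still differed by 1.09 on the log2 scale (78.4 ± 21.9 in AUG_WT and 36.4 ± 7.70 in del7_WT, SD, n = 4; exact permutation p = 0.0286, the smallest possible), so the sum neither bears this out nor excludes it. In del7, replicate 3 alone had high Rpl26, 46.2 CPM, where the lowest was 1.86 CPM. That library also had the lowest Gm15772 in del7, 18.8 CPM, against 30.4 to 34.8 CPM in the others. A single library does not decide whether reads trade places. The mouse line, which the design names, stays open as a biological difference and was not tested.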
